A study of Mus musculus with 20 samples.

How the data were processed

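Total RNA from bladders and metastases of mice was extracted with a kit for formalin-fixed, paraffin-embedded tissue, and 12 ng per sample was labelled and hybridised to an Affymetrix whole-transcript array, per the labels' protocols. The deposited values are on the log2 scale, 1 per row and array, and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions, settings and any batch adjustment are not given in the sources used here. RMA corrects background, quantile-normalizes arrays and summarises probes, so differences in overall RNA amount are removed. The deposited table holds 65956 rows and 20 columns of values from 2.29 to 22.0, with none missing. In 284 rows some values exceed 16, the log2 limit of a 16-bit scanner, so a step beyond the named ones is open for such rows. No scanner files were used here, so signal over background could not be computed.

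Rows were named through the platform annotation: 30604 rows had 1 gene symbol, 2146 had several and were not used, and 33206 rows were not listed and stay unnamed here. Symbols of 22818 rows were looked up by gene ID in a table of the assembly GRCm38.p6, which updated 827 rows; no coordinates were used. This gave 30142 genes. For the 355 genes with several rows, the row with the highest mean over all arrays was kept.

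Groups came from the sample labels. limma (version 3.58.1, R 4.3.3) fitted group means with lmFit and eBayes to the 19 arrays of the 4 replicated groups, which share 1 estimate of the spread, with no covariates. Two-sided p-values were adjusted by the Benjamini-Hochberg method in each of 5 comparisons, and a gene was called at adjusted p under 0.05 with no fold threshold. The treated metastasis is a single sample and entered no test. Differences are on the log2 scale, first group minus second, so that 1 is 2-fold.

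The 30 gene lists were written before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. They covered the engineered loci, the G9a-DNMT network, E2F and replication, mitosis, p53 targets, interferon response and antigen presentation. Further lists held stress programs (immediate early genes, unfolded protein response, hypoxia), germline genes silenced by methylation and 6 kinds of immune markers. The remaining lists held markers of epithelia, stroma and other organs. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 150 pairs of list and comparison, and again with an estimated correlation and with fry. In these data 41 pairs passed with the preset correlation, 0 with an estimated one and 0 with fry, whose PValue asks whether a list's genes move one way on balance and whose PValue.Mixed, also 0, whether they change in either direction. A difference given for a list is the mean of its members' log2 differences; for the 41 called pairs its sign equals that of the median and of the test. Exact two-sided permutation tests of the same 150 list means gave 3 with a raw p under 0.05 and none after adjustment, the lowest adjusted p being 0.927. With only 56 to 792 splits per comparison, no list could pass alone after adjustment over 150 tests. The lack of adjusted passes in these permutation tests therefore says little.

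Named genes followed this rule. Where genes passed, the 5 largest rises and 5 largest falls were named, leaving out predicted and small RNA genes; where none passed, the 5 with the smallest p. The engineered loci, Ehmt2 and Dnmt1 were always named. From each list described, the 3 members with the largest change among those that passed were named, or else the 2 with the smallest p. For the treated metastasis, the 5 highest and 5 lowest differences from the mean of the untreated metastases among genes outside their range were named. Xist, Acta2, Alb and the genes called without the near-mean arrays were chosen after their values were seen.

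Near-mean arrays were defined after the data were seen as those whose deviations from the mean of all arrays correlate with no other array above 0.2; no group was used to define them. Alternatives tried were the 2 groups alone, array weights, a trended and robust prior, quantile normalization once more, centring on array medians, dropping dim genes, averaging or keeping all rows of a gene, a 2-fold threshold, the replicate number as a block and leaving out each array. Added later were leaving out the near-mean arrays, the same with each further array left out in turn and with array weights, leaving out 7 of the 8 (keeping bladder tumor 3) with and without array weights, that set of 8 as a covariate, that set alone, the mean of 1542 chemosensory receptor genes as a covariate, and dropping predicted, small RNA and chemosensory genes.

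The fit was tested on simulated data with the real gene means and residual spread, 30142 genes and 200 changed ones. It recovered 83.6% of genes changed by 1 on the log2 scale in tumor against control, 76.1% in treated bladder against tumor, 70.1% in treated bladder against control, 83.6% in metastasis against tumor and 74.6% in metastasis against control. With no change, it called 0 genes and 0 lists in each. The simulated spread is independent between genes, which real tissue markers are not, and uses limma's moderated variance of each gene. A gene thus has the same simulated spread in every array, and the near-mean arrays are not modelled. In those arrays smooth muscle genes differed little between groups, while they differed more among the other arrays. The recovery rates therefore do not show how many changes of this size the real arrays would reveal. Figures were drawn with matplotlib 3.10.9.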

Results

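RNA from 20 tissue samples of FVB/N mice was measured on whole-transcript microarrays. All mice shared a genotype that includes floxed alleles of Rb and the loss of p107, a relative of Rb. An adenovirus coding for Cre recombinase, which deletes floxed genes, had been placed in the bladder of some of them to start tumors. The groups were control bladder (n = 5), bladder tumor (n = 7), treated bladder (n = 3), metastasis (n = 4) and treated metastasis (n = 1). Treated mice had received CM272, a dual inhibitor of the histone methyltransferase G9a and of DNA methyltransferases, at 5 mg/kg per day for 30 days, with cisplatin at 6 mg/kg once per week. The labels number the samples of a group without stating that each came from another animal, so p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision, and array medians ran from 5.07 to 5.42 on the log2 scale.

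The arrays fell into 2 sets that crossed the groups. In 8 arrays (control bladder 4, 5 and 6, bladder tumor 3, 4 and 5, metastasis 3 and 4), the deviation of each gene from its mean over all arrays correlated with that of no other array above r = 0.14, across genes. In the other 12 the highest such correlation ran from 0.33 to 0.61. Xist, the RNA that silences one X chromosome in females, read 10.8 and 10.9 in control bladder 1 and 2, and 4.47 to 6.44 in the other 10 arrays of this set. The 8 near-mean arrays read 5.82 to 6.09, close to the mean of 6.12 over the other 12. Acta2, smooth muscle actin, spanned 5.94 to 12.2 in the 12 arrays and 7.45 to 8.14 in the 8. All 3 treated bladders and the treated metastasis belonged to the 12. Because of this split, gene counts and the called lists are given over all arrays and again without the 8.

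**Figure D1:**
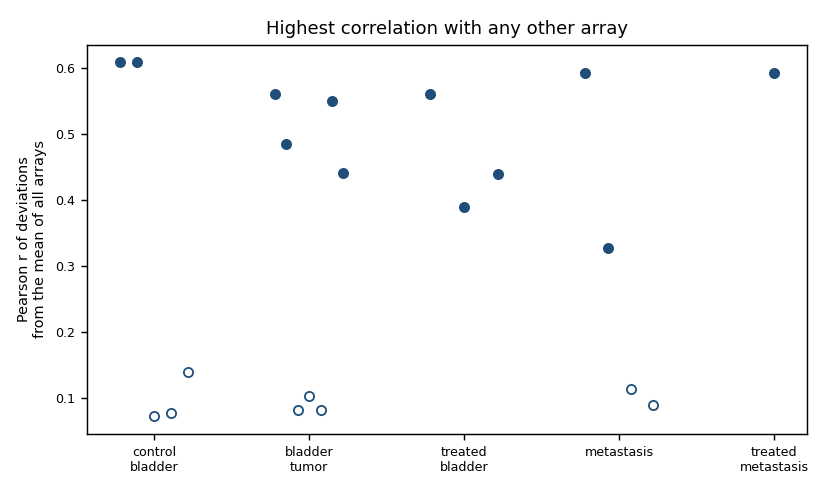
For each array (one point, by group on the x axis), the y axis gives the highest Pearson r, across genes, between its deviations from the mean of all arrays and those of any other array. The 8 open points, the near-mean arrays, lie at or below 0.14, and the 12 filled points at or above 0.33.

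The engineered and targeted genes were examined first. Of the engineered loci, Rb1 and Rbl1 (p107) were analysed here. Rbl1 read 6.51 ± 0.23 in control bladder (SD, n = 5), 6.63 ± 0.29 in bladder tumor (n = 7), 6.41 ± 0.52 in treated bladder (n = 3) and 6.99 ± 0.87 in metastasis (n = 4). Rb1 read 6.18 ± 0.19, 5.99 ± 0.33, 6.01 ± 0.15 and 6.05 ± 0.20 in the same order. Whether these probes lie in the deleted parts of the genes is not given in the sources used here, so the values do not check the genotype. Ehmt2, which codes for G9a, read 6.80 ± 0.14 in control bladder (n = 5), 6.77 ± 0.12 in tumor (n = 7), 6.79 ± 0.17 in treated bladder (n = 3) and 6.83 ± 0.16 in metastasis (n = 4). Dnmt1, the maintenance DNA methyltransferase, read 7.03 ± 0.33, 7.50 ± 0.55, 7.11 ± 0.61 and 7.50 ± 0.55. None of these 4 genes passed in any comparison. The list of engineered loci passed in none; its mean in tumor minus control was -0.04, with a camera adjusted p of 0.648. The G9a-DNMT list of 9 genes passed in none either. Its mean in tumor minus control was 0.14, with a camera adjusted p of 0.124. The list of p53 targets, with 18 members measured, also passed in none. Its mean in tumor minus control was -0.04, with an exact permutation p of 0.515. In treated bladder minus tumor it was 0.03, with an exact permutation p of 0.725.

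The first comparison asked what separates tumor from control bladder. Cell cycle genes were higher in tumor: all 23 measured members of the mitosis list and all 23 of the E2F and DNA replication list had higher means. The mean log2 difference was 0.37 for mitosis (adjusted p = 1.63e-08) and 0.27 for E2F and replication (adjusted p = 8.66e-07). All 16 smooth muscle genes were lower, by a mean of -0.69 (adjusted p = 2.54e-05), and 10 of 12 endothelial genes were lower, by a mean of -0.14 (adjusted p = 0.00197). Neutrophil genes were higher by 0.49 (14 of 15 members, adjusted p = 0.000352), interferon response genes by 0.16 (23 of 29, adjusted p = 0.00233), immediate early genes by 0.16 (10 of 12, adjusted p = 0.00858) and lung epithelium genes by 0.13 (11 of 12, adjusted p = 0.0408). With a correlation estimated per list no call held: adjusted p = 0.845 with an estimated correlation for interferon response, and 0.775 for each of the other 7 lists. With single arrays left out, calls were lost for interferon response (0.07 without bladder tumor 6), endothelium (-0.07 without control bladder 1), immediate early genes (0.12 without control bladder 1 and 0.12 without bladder tumor 6) and lung epithelium (0.09 without bladder tumor 1, 0.11 without bladder tumor 4, 0.10 without control bladder 4, 0.13 without control bladder 6). Smooth muscle stayed called at -0.45 without control bladder 1, -0.44 without control bladder 2 and -1.10 without bladder tumor 7, and neutrophils at 0.31 without bladder tumor 6.

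No single gene passed in tumor against control. limma called 0 of 30142 genes at adjusted p under 0.05, with 1291 at an unadjusted level of 0.05 against 1507.1 expected by chance, and 0 were called with array weights or with a trended, robust prior. The 5 genes with the smallest p were Gm15946 (0.70 higher), Gm10238 (-0.70), Ropn1l (0.37), LOC545763 (0.86) and Gm15593 (0.82), with adjusted p from 0.536 to 0.999. Values for members of the lists carried wide errors. Cdc20, an activator of the anaphase-promoting complex, was at 5.80 ± 0.47 in tumor (n = 7) and 5.20 ± 0.28 in control (n = 5), and Birc5, the survivin gene, at 5.20 ± 0.29 and 4.91 ± 0.20. Mcm2, a part of the replicative helicase, was at 5.50 ± 0.33 and 5.12 ± 0.28, and Pole, a catalytic subunit of a replicative DNA polymerase, at 5.85 ± 0.42 and 5.49 ± 0.29. S100a9, a neutrophil alarmin, was at 8.31 ± 2.06 and 6.10 ± 1.65, and Camp, an antimicrobial peptide, at 6.02 ± 0.21 and 5.74 ± 0.23. Acta2 was at 7.73 ± 2.09 and 9.19 ± 1.66, and Pcp4, a calmodulin regulator, at 7.48 ± 1.15 and 8.46 ± 1.24. Tek, the angiopoietin receptor, was at 5.78 ± 0.14 and 6.22 ± 0.39, and Kdr, a VEGF receptor, at 5.74 ± 0.08 and 5.97 ± 0.25. Cxcl10, an interferon-induced chemokine, was at 5.24 ± 0.42 and 4.77 ± 0.15, Rtp4 at 5.80 ± 0.25 and 5.27 ± 0.23, and Jun at 5.31 ± 0.18 and 4.95 ± 0.21. None of these members passed, over all genes or adjusted over the list alone.

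No lymphocyte list passed in tumor against control. Mean differences were 0.15 for B and plasma cells (adjusted p = 0.164), 0.05 for T cells (0.573) and 0.05 for cytotoxic and NK cells (0.637). Immune checkpoints differed by -0.00 (adjusted p = 0.984) and antigen presentation by 0.01 (0.723). Without the 8 near-mean arrays the fit holds 4 tumors and only 2 controls, control bladders 1 and 2, which read high for Xist and low for the Y-linked genes Eif2s3y (mean 5.02) and Uty (5.21). Xist was the 1 gene called, at -6.08 (adjusted p = 3.59e-06), and every shift against control in this fit rests on these 2 arrays. No other array read Xist above 6.44. A difference from control in this fit, in any comparison, therefore cannot be told apart from a difference of sex. Differences from all 5 controls also draw on these 2 arrays and are not free of this limit. The count depends on single arrays and on weights: with 1 further array left out it was 59, all lower, without bladder tumor 7, 2 without control bladder 2 and 1 in the other 9 fits, and with array weights it was 48 (6 higher, 42 lower). In the fit without the 8 the mean differences were 0.83 for mitosis, 0.62 for E2F and replication, 1.06 for neutrophils, 0.34 for interferon response, 0.29 for immediate early genes, -1.69 for smooth muscle and -0.36 for endothelium. Macrophage and dendritic cell genes (0.56, adjusted p = 0.000117), luminal urothelium genes (-0.73, adjusted p = 0.00809), hypoxia and glycolysis genes (0.35, adjusted p = 0.0206) and adipocyte genes (-0.19, adjusted p = 0.0282) then passed as well, lung epithelium did not (0.12, adjusted p = 0.482), and 11 lists were called in all. With 1 further array left out, 6 of the 11 stayed called in every fit: mitosis, E2F, macrophages, neutrophils, smooth muscle and endothelium. Without bladder tumor 6, calls were lost for interferon response (0.16), immediate early genes (0.21), luminal urothelium (-0.34), hypoxia (0.10) and adipocytes (-0.08). Luminal urothelium was also lost without bladder tumor 2 (-0.46) and stood at -1.41 without bladder tumor 7, where adipocytes (-0.23) were lost. Without control bladder 2, luminal urothelium (-0.60), hypoxia (0.31) and adipocytes (-0.18) were lost, and without control bladder 1 adipocytes (-0.20). None of the 11 held with an estimated correlation, where the lowest adjusted p was 0.291. The mean of 1542 chemosensory receptor genes, expected to be silent in bladder and read as background, was 4.93 ± 0.19 in tumor (n = 7) and 4.89 ± 0.04 in control (n = 5), with an exact two-sided permutation p of 0.609; with it as a covariate, lung epithelium was no longer called (0.10, adjusted p = 0.16).

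**Figure D2:**
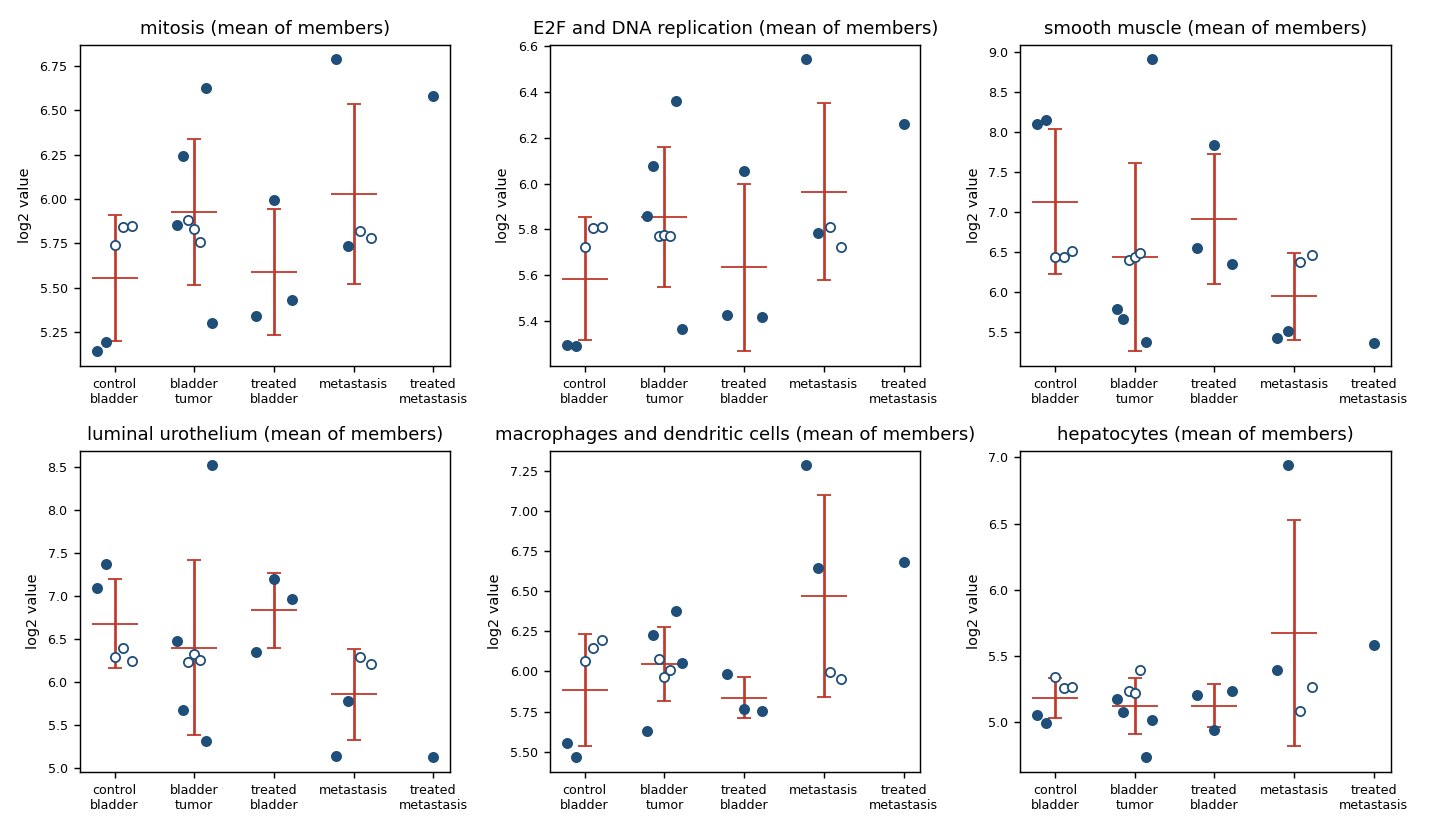
Each point is the mean log2 value (y axis) of the measured members of a list in one array, by group on the x axis; open points are the 8 near-mean arrays, and red bars give the mean and SD of groups with more than 1 array. In the mitosis panel control bladders 1 and 2 are the 2 lowest arrays, and in the smooth muscle panel bladder tumor 7 lies highest, at 8.91.

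The second comparison asked how tumor-bearing bladders differed after treatment. Cell cycle genes were lower in treated bladder than in tumor: all 23 mitosis genes, by a mean of -0.34 (adjusted p = 1.57e-12), and all 23 E2F and replication genes, by -0.22 (adjusted p = 1.81e-07). Luminal urothelium genes were higher by 0.43 (17 of 18, adjusted p = 0.000542) and smooth muscle genes by 0.47 (15 of 16, adjusted p = 0.00233). Fibroblast and matrix genes were lower by -0.23 (12 of 15, adjusted p = 0.000483), immediate early genes by -0.15 (12 of 12, adjusted p = 0.00145), hypoxia and glycolysis genes by -0.15 (12 of 14, adjusted p = 0.00858) and unfolded protein response genes by -0.16 (13 of 13, adjusted p = 0.021). Macrophage and dendritic cell genes (-0.21, adjusted p = 0.0211), neutrophil genes (-0.24, adjusted p = 0.0317), interferon response genes (-0.08, adjusted p = 0.0333) and EMT regulators (-0.19, adjusted p = 0.0346) were lower too. With a correlation estimated per list none of the 12 calls held: adjusted p = 0.888 with an estimated correlation for interferon response, 0.845 for smooth muscle and 0.775 for the other 10.

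In treated bladder against tumor, mitosis was the only list of the 12 called in each of the 19 fits that left out 1 array, at -0.22 without bladder tumor 6, -0.21 without treated bladder 1 and -0.54 without treated bladder 2. Without bladder tumor 6, calls were lost for fibroblasts (-0.07), hypoxia (-0.01), unfolded protein response (-0.05), EMT regulators (-0.05), neutrophils (-0.06), macrophages (-0.16), interferon response (0.01) and smooth muscle (0.30), while E2F (-0.13) and luminal urothelium (0.25) stayed called. Without treated bladder 1, they were lost for fibroblasts (-0.08), hypoxia (-0.07), unfolded protein response (-0.07), EMT regulators (-0.12), interferon response (0.05) and immediate early genes (-0.08), while E2F (-0.12) and luminal urothelium (0.68) stayed called. Without treated bladder 2, they were lost for smooth muscle (0.01), luminal urothelium (0.25), macrophages (-0.18) and neutrophils (-0.20). In that fit E2F (-0.43), fibroblasts (-0.41), hypoxia (-0.33), interferon response (-0.30), EMT regulators (-0.28) and unfolded protein response (-0.28) were further from 0. Without treated bladder 3, calls were lost for E2F (-0.11), hypoxia (-0.04), unfolded protein response (-0.13), EMT regulators (-0.16), interferon response (-0.00), macrophages (-0.17) and neutrophils (-0.22), and smooth muscle was at 0.76. Without bladder tumor 2, they were lost for smooth muscle (0.35), interferon response (-0.08), macrophages (-0.18) and neutrophils (-0.22). Smooth muscle was also lost without bladder tumor 1 (0.37), macrophages without bladder tumor 3 (-0.21) and interferon response without bladder tumor 4 (-0.09). Calls held at -0.37 for fibroblasts and -0.28 for EMT regulators without bladder tumor 1, and at 0.89 for smooth muscle, 0.79 for luminal urothelium and -0.14 for interferon response without bladder tumor 7.

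No single gene passed in treated bladder against tumor. limma called 0 of 30142 genes, with 147 at an unadjusted level of 0.05 against 1507.1 expected by chance, and 0 were called with array weights, with a trended and robust prior or without the 8 near-mean arrays. The 5 genes with the smallest p, all with an adjusted p of 1.0, were the olfactory receptor genes Olfr981 (0.83 higher) and Olfr1384 (1.01) and the predicted genes Gm23271 (0.92), Gm14355 (1.12) and Gm24796 (1.15). Bub1b, a spindle checkpoint kinase, was at 5.27 ± 0.17 in treated bladder (n = 3) and 5.55 ± 0.29 in tumor (n = 7), and Cdc20 at 5.41 ± 0.37 and 5.80 ± 0.47. Mcm2 was at 5.20 ± 0.35 and 5.50 ± 0.33. Krt7, a simple epithelial keratin, was at 7.30 ± 0.60 and 6.86 ± 0.62, and Cldn4, a tight junction protein, at 7.30 ± 1.07 and 6.68 ± 1.08. Actg2, enteric smooth muscle actin, was at 8.36 ± 2.08 and 7.14 ± 2.06, and Myh11, smooth muscle myosin, at 7.99 ± 1.52 and 6.95 ± 2.07. Col6a1 was at 6.35 ± 0.09 and 6.68 ± 0.37, and Col3a1 at 6.86 ± 0.18 and 7.25 ± 0.67. Hspa5, an endoplasmic reticulum chaperone, was at 6.72 ± 0.43 and 7.16 ± 0.63, Calr, calreticulin, at 7.73 ± 0.48 and 8.14 ± 0.65, and Fn1, fibronectin, at 8.61 ± 0.97 and 9.41 ± 1.47.

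The series title names an immune-mediated regression, so the immune lists are given in full. T cell genes differed by 0.01 between treated bladder and tumor (adjusted p = 0.723), cytotoxic and NK cell genes by -0.03 (0.801), immune checkpoint genes by -0.01 (0.978), antigen presentation genes by -0.07 (0.0997) and B and plasma cell genes by -0.13 (0.131). Cd3e, a T cell receptor subunit, was at 5.05 ± 0.28 in treated bladder (n = 3) and 5.15 ± 0.24 in tumor (n = 7). Cd8b1 was at 5.17 ± 0.11 and 5.35 ± 0.37, Ifng, interferon gamma, at 4.43 ± 0.23 and 4.70 ± 0.29, Ccl5 at 5.17 ± 0.12 and 5.51 ± 0.45, and Pdcd1, the PD-1 gene, at 5.33 ± 0.25 and 5.17 ± 0.11. Germline genes silenced by DNA methylation, which an inhibitor of DNA methyltransferases could touch, differed by -0.00 (18 members, adjusted p = 0.919). For cytotoxic and NK cells, immune checkpoints and germline genes the mean, the median and the test differed in sign. The chemosensory receptor mean was 5.02 ± 0.21 in treated bladder (n = 3) and 4.93 ± 0.19 in tumor (n = 7), with an exact two-sided permutation p of 0.5. With that mean as a covariate, the mitosis difference was -0.23 (adjusted p = 4.45e-05), the E2F difference -0.13 (adjusted p = 0.00882), the fibroblast difference -0.07 (adjusted p = 0.303) and the interferon difference 0.01 (adjusted p = 0.692); macrophages, neutrophils, EMT regulators, unfolded protein response and hypoxia also lost their calls. Without the 8 near-mean arrays all 12 lists stayed called in the same direction: mitosis (-0.42), E2F (-0.28), interferon response (-0.14), macrophages (-0.23), neutrophils (-0.41), luminal urothelium (0.34), EMT regulators (-0.22), smooth muscle (0.48), fibroblasts (-0.31), immediate early genes (-0.16), unfolded protein response (-0.22) and hypoxia (-0.22). With endothelium (0.09) and skeletal muscle (-0.17), 14 lists were called. None of the 14 held with an estimated correlation, where the lowest adjusted p was 0.359.

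Without the 8 near-mean arrays and 1 further array, mitosis was again the only list of the 14 called in each of the 11 fits, for treated bladder against tumor. It stood at -0.21 without bladder tumor 6 and -0.65 without bladder tumor 7. Without bladder tumor 6, only 3 lists were called in place of 14. Calls were lost there for E2F (-0.13), interferon response (0.04), macrophages (-0.13), neutrophils (-0.11), luminal urothelium (-0.06), EMT regulators (0.03), smooth muscle (0.12), fibroblasts (-0.01), skeletal muscle (-0.08), immediate early genes (-0.08), unfolded protein response (-0.01) and hypoxia (0.03). Without treated bladder 1, they were lost for interferon response (0.00), EMT regulators (-0.15), fibroblasts (-0.16), immediate early genes (-0.09), unfolded protein response (-0.13) and hypoxia (-0.14), while E2F (-0.18) and luminal urothelium (0.58) stayed called. Without treated bladder 2, they were lost for macrophages (-0.20), neutrophils (-0.37), luminal urothelium (0.16), smooth muscle (0.01), endothelium (0.03) and skeletal muscle (-0.13). E2F (-0.49), interferon response (-0.35), fibroblasts (-0.49), unfolded protein response (-0.33) and hypoxia (-0.40) were then further from 0. Without treated bladder 3, 9 lists were called, not 14, and interferon response (-0.06), macrophages (-0.19), EMT regulators (-0.20), unfolded protein response (-0.19) and hypoxia (-0.11) were lost, with E2F at -0.17 and smooth muscle at 0.76. Without bladder tumor 1, luminal urothelium (0.33), smooth muscle (0.26), endothelium (0.07) and skeletal muscle (-0.19) were lost. Macrophages (-0.38), neutrophils (-0.64), EMT regulators (-0.42), fibroblasts (-0.61), unfolded protein response (-0.35) and hypoxia (-0.34) stayed called. Without bladder tumor 2, macrophages (-0.18), luminal urothelium (0.06), smooth muscle (0.22) and endothelium (0.05) were lost. Without bladder tumor 7, immediate early genes (-0.14) were lost, and E2F (-0.46), interferon response (-0.27), luminal urothelium (1.01) and smooth muscle (1.30) stayed called. In all 11 fits limma called 0 genes.

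A count of genes that changed in tumor and changed the other way with treatment was also planned, and 0 genes were called in both comparisons. At an unadjusted level of 0.05, 14 genes were higher in tumor and lower with treatment, and 29 were lower in tumor and higher with treatment. Independent lists of these sizes would share 0.441 and 2.51 genes. Simulated unchanged groups that share the tumor arrays gave 107.7 and 109.35 on average over 20 simulations, since a chance deviation of the shared arrays enters both comparisons with opposite sign. In the real data, however, only 19 genes were lower and 128 higher with treatment at this level. An overlap with the 19 could never reach 107.7. The simulation therefore cannot tell whether the real overlaps lie above or below chance. With the tumor arrays split so that the comparisons shared none, 35 splits gave 3.03 and 5.23 genes on average.

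Treated bladder was also set against control bladder, which asks how far treated bladders stood from tissue without induced tumors. Fibroblast and matrix genes were lower in treated bladder by -0.28 (13 of 15, adjusted p = 0.00198), EMT regulators by -0.17 (9 of 12, adjusted p = 0.0145) and unfolded protein response genes by -0.15 (9 of 13, adjusted p = 0.0313), while neutrophil genes were higher by 0.25 (12 of 15, adjusted p = 0.0433). Each had an adjusted p = 0.775 with an estimated correlation. Without treated bladder 1, all 4 calls were lost: fibroblasts (-0.13), EMT regulators (-0.09), unfolded protein response (-0.06) and neutrophils (0.20). Without treated bladder 2, neutrophils (0.28) were lost, and fibroblasts (-0.46), EMT regulators (-0.26) and unfolded protein response (-0.26) stayed called. Without treated bladder 3, EMT regulators (-0.14), unfolded protein response (-0.12) and neutrophils (0.27) were lost. Fibroblasts (-0.18) and neutrophils (0.14) were lost without control bladder 1, neutrophils (0.16) without control bladder 2, and at an unchanged 0.25 without bladder tumor 1, bladder tumor 3, metastasis 1 or metastasis 3, which enter only the shared spread, and unfolded protein response without control bladder 4 (-0.14) or 6 (-0.12). Mitosis (0.04, adjusted p = 0.8), E2F and replication (0.05, adjusted p = 0.408) and smooth muscle (-0.22, adjusted p = 0.0646) did not pass. Dcn, decorin, was at 8.22 ± 0.56 in treated bladder (n = 3) and 9.25 ± 0.69 in control (n = 5), Fbln1 at 5.83 ± 0.30 and 6.30 ± 0.77, Twist2 at 4.88 ± 0.10 and 5.16 ± 0.24, Mmp2, a matrix protease, at 6.29 ± 0.14 and 6.77 ± 0.48, Herpud1 at 6.30 ± 0.28 and 6.64 ± 0.28, and Trem1 at 5.42 ± 0.11 and 5.11 ± 0.09.

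limma called 0 genes in treated bladder against control, with 230 at an unadjusted level of 0.05, and 0 with array weights or a trended, robust prior. The smallest p belonged to Gm24593 (1.28 higher), Gm4911 (0.66), Gm23760 (0.82), Olfr1384 (1.03) and the vomeronasal receptor gene Vmn1r129 (0.89), each with an adjusted p of 1.0. The chemosensory receptor mean was 0.13 higher in treated bladder, with an exact two-sided permutation p of 0.179. With it as a covariate the EMT difference was 0.05, the unfolded protein response difference 0.03 and the fibroblast difference -0.04, and none of the 3 was still called, while the neutrophil difference was 0.42 (adjusted p = 0.000715). Without the 8 near-mean arrays, and so with control bladders 1 and 2 alone, 9 lists were called, and 0 with an estimated correlation (lowest adjusted p = 0.291). Mitosis (0.42, adjusted p = 2.95e-05), E2F and replication (0.34, adjusted p = 1.53e-05) and smooth muscle (-1.21, adjusted p = 1.74e-10) were among them, as were neutrophils (0.65), fibroblasts (-0.52), macrophages (0.33), interferon response (0.20), endothelium (-0.27) and adipocytes (-0.23). EMT regulators (-0.15, adjusted p = 0.0602) and unfolded protein response (-0.10, adjusted p = 0.186) were not called. Xist was the 1 gene called, at -4.82 (adjusted p = 5.70e-05), and with 1 further array left out the count was 2, both lower, without bladder tumor 7 and 1 in the other 10 fits. Without treated bladder 2 as well, mitosis (0.22), E2F (0.13), interferon response (-0.01) and adipocytes (-0.14) lost their calls; without control bladder 1 fibroblasts did (-0.36), with endothelium at -0.17, and without control bladder 2 (0.19), bladder tumor 1 (0.20) or bladder tumor 2 (0.20) interferon response did. Interferon response stood at 0.34 without treated bladder 1.

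Metastases were compared with bladder tumors to ask what differs at the distant site. Macrophage and dendritic cell genes were higher in metastasis by 0.42 (13 of 18, adjusted p = 0.000483), hepatocyte genes by 0.55 (11 of 13, adjusted p = 0.00133) and EMT regulators by 0.21 (8 of 12, adjusted p = 0.0346). Luminal urothelium genes were lower by -0.54 (16 of 18, adjusted p = 0.00198), basal and squamous genes by -0.30 (15 of 17, adjusted p = 0.0346), smooth muscle genes by -0.49 (16 of 16, adjusted p = 0.0421), B and plasma cell genes by -0.18 (14 of 14, adjusted p = 0.0426) and skeletal muscle genes by -0.17 (9 of 10, adjusted p = 0.0497). With a correlation estimated per list none of the 8 held: adjusted p = 0.888 with an estimated correlation for smooth muscle, 0.793 for luminal urothelium and for B and plasma cells, and 0.775 for the other 5. Each of the 8 calls was lost in some fit that left out 1 array. Without metastasis 1, this held for macrophages (0.15), luminal urothelium (-0.31), basal and squamous genes (-0.22), smooth muscle (-0.32), EMT regulators (0.11), B and plasma cells (-0.17) and skeletal muscle (-0.10). Without metastasis 2, it held for hepatocytes (0.13), basal and squamous genes (-0.24), smooth muscle (-0.35), EMT regulators (0.17), B and plasma cells (-0.13) and skeletal muscle (-0.15). Without bladder tumor 1, it held for B and plasma cells (-0.09), basal and squamous genes (-0.24), EMT regulators (0.11) and skeletal muscle (-0.16), and without bladder tumor 7 for luminal urothelium (-0.19), smooth muscle (-0.08) and EMT regulators (0.20). B and plasma cells (-0.14) and EMT regulators (0.19) were lost without bladder tumor 2, smooth muscle (-0.50) and skeletal muscle (-0.17) without bladder tumor 3, smooth muscle (-0.49) without bladder tumor 5, and EMT regulators (0.24) without metastasis 3. Without bladder tumor 6, basal and squamous genes (-0.35) and skeletal muscle (-0.11) were lost, and EMT regulators stood at 0.34. Through the shared spread alone, skeletal muscle (-0.17) was also lost without any 1 of the 5 control bladders, treated bladder 1 or treated bladder 3, and B and plasma cells (-0.18) without control bladder 1.

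Without the 8 near-mean arrays, 4 genes were called in metastasis against tumor, all higher, and they were named because they are so few. Ahsg, the liver glycoprotein fetuin-A, was 4.81 higher (adjusted p = 0.000243), Lyz1, a lysozyme gene, 3.8 (adjusted p = 0.00104), Ctsk, the protease cathepsin K, 2.19 (adjusted p = 0.00104), and Prg4, lubricin, 2.03 (adjusted p = 0.0101). With 1 further array left out the count was 41 without metastasis 2, 13 without metastasis 1, 6 without bladder tumor 6, 5 without bladder tumor 2 and 4 in the other 7 fits, all of them higher. Where 1 metastasis is left, it is taken to vary like the arrays of the other groups. In metastasis 1 and 2 Ahsg read 10.6 and 10.4, Lyz1 11.03 and 10.61, and Prg4 7.59 and 7.82. Over all arrays limma called 0 genes, with 1810 at an unadjusted level of 0.05, 2 with array weights, 2 without bladder tumor 6, 2 without control bladder 5 and 0 with a trended, robust prior; Ahsg then differed by 2.48 (adjusted p = 0.825) and was the only hepatocyte gene to pass adjusted over the list alone. The 5 genes with the smallest p were Hnrnph2, an RNA-binding protein (0.74 higher, adjusted p = 0.0591), the defensin gene Defb5 (-1.15, adjusted p = 0.0591), Gm5945 (1.10, adjusted p = 0.412), the sphingosine receptor gene S1pr5 (0.61, adjusted p = 0.412) and Tram1l1 (-0.61, adjusted p = 0.588). With array weights the 2 called genes were Hnrnph2 (0.72, adjusted p = 0.0233) and Defb5 (-1.24, adjusted p = 0.00842).

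**Figure D3:**
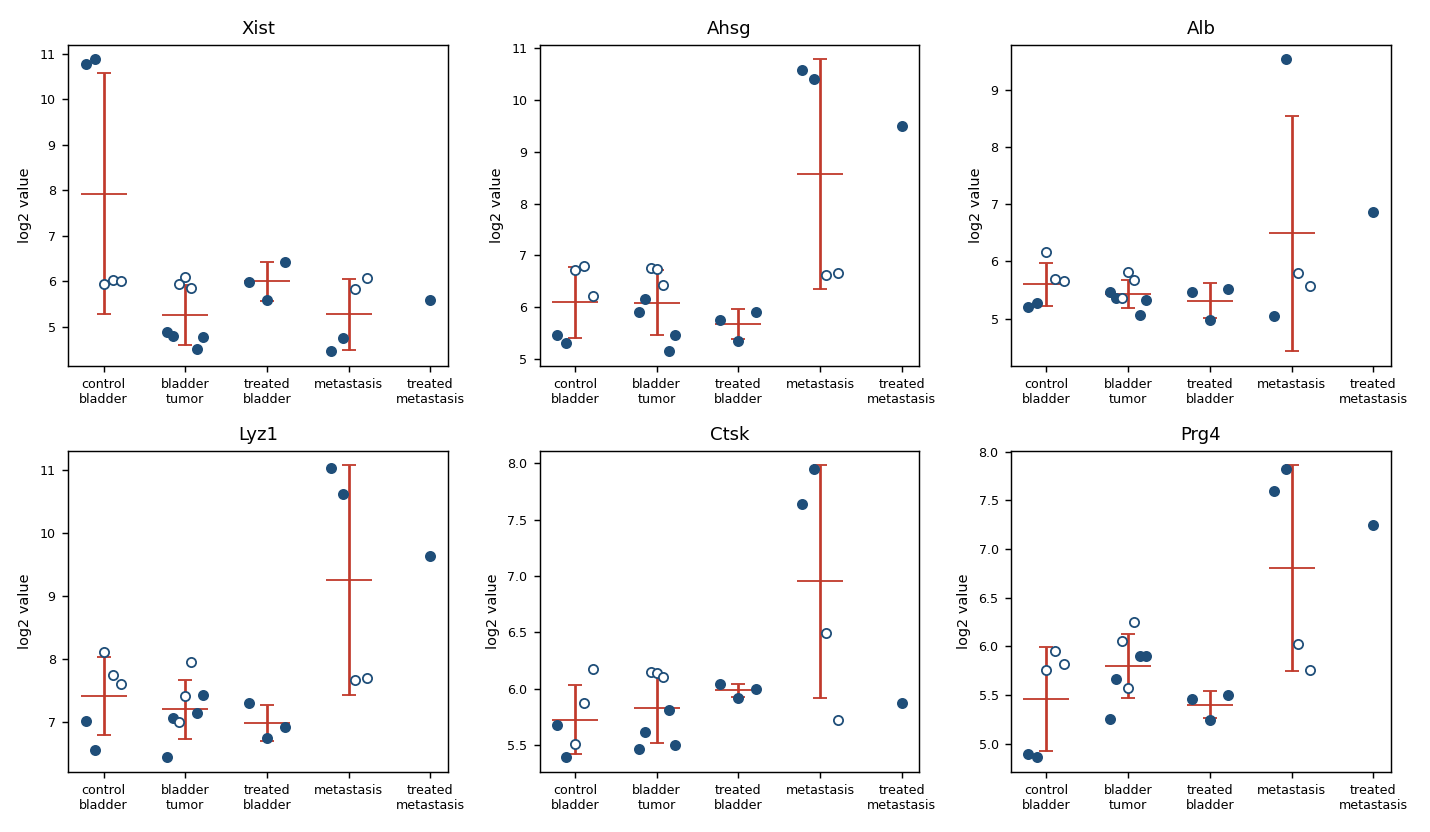
Log2 values (y axis) of 6 genes in each array, by group on the x axis; open points are the 8 near-mean arrays, and red bars give the mean and SD of groups with more than 1 array. Ahsg, Lyz1 and Prg4 are high in metastases 1 and 2 and in the treated metastasis, Alb reads 9.53 in metastasis 2 and 5.06 in metastasis 1, and Xist is high in control bladders 1 and 2.

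Members of the lists showed the same spread. Lyz2, a macrophage lysozyme, was at 11.01 ± 1.93 in metastasis (n = 4) and 9.20 ± 1.22 in tumor (n = 7), and Csf1r, the receptor for macrophage colony-stimulating factor, at 6.47 ± 0.54 and 6.03 ± 0.25. Cldn4 was at 5.21 ± 0.73 and 6.68 ± 1.08, Elf3, an epithelial transcription factor, at 4.74 ± 0.17 and 5.25 ± 0.42, Trp63, the basal cell regulator p63, at 5.17 ± 0.25 and 5.72 ± 0.44, and Krt5 at 5.79 ± 0.80 and 7.01 ± 1.35. Cdh2, N-cadherin, was at 6.72 ± 0.70 and 5.93 ± 0.34, and Mmp9 at 5.77 ± 0.78 and 5.10 ± 0.25. Cd79a was at 5.22 ± 0.12 and 5.49 ± 0.23. None of these passed. T cell genes differed by -0.06 (adjusted p = 0.481) and cytotoxic and NK cell genes by -0.10 (adjusted p = 0.142). Without the 8 arrays the macrophage difference was 0.89 (adjusted p = 4.81e-09), with 8 of 18 members passing adjusted over the list alone. All 8 lists stayed called: hepatocytes (1.17), EMT regulators (0.36), luminal urothelium (-1.04), basal and squamous genes (-0.55), smooth muscle (-0.96), B and plasma cells (-0.34) and skeletal muscle (-0.37) were the others. E2F and replication (0.25), mitosis (0.26) and antigen presentation (0.38) passed too, so that 11 lists were called; 0 held with an estimated correlation (lowest adjusted p = 0.291). With 1 further array left out, macrophages (0.57 without metastasis 1), luminal urothelium (-0.36 without bladder tumor 7) and basal and squamous genes stayed called in every fit. Without bladder tumor 7, 6 lists were called, not 11, and E2F (0.07), mitosis (0.02), antigen presentation (0.38), EMT regulators (0.34) and smooth muscle (-0.14) were lost. Without metastasis 1, E2F (-0.13), mitosis (-0.27) and antigen presentation (0.01) were lost and hepatocytes stood at 1.94. Without metastasis 2, hepatocytes (0.39), smooth muscle (-1.0) and B and plasma cells (-0.27) were lost, with E2F at 0.63, mitosis at 0.78 and antigen presentation at 0.75. Without bladder tumor 1, mitosis (0.21), antigen presentation (0.26), B and plasma cells (-0.19) and EMT regulators (0.16) were lost, and without bladder tumor 2, B and plasma cells (-0.28) and EMT regulators (0.32). Without bladder tumor 6, skeletal muscle (-0.28) was lost, with E2F at 0.40, mitosis at 0.46 and EMT regulators at 0.62. The chemosensory receptor mean was 4.85 ± 0.12 in metastasis (n = 4) against 4.93 ± 0.19 in tumor (n = 7), with an exact two-sided permutation p of 0.448; with it as a covariate, B and plasma cells (adjusted p = 0.293), EMT regulators (adjusted p = 0.346) and skeletal muscle (adjusted p = 0.0527) were no longer called.

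The last comparison asked how metastases differ from control bladder. Mitosis genes were higher in metastasis by 0.48 (22 of 23, adjusted p = 1.63e-08), E2F and replication genes by 0.38 (23 of 23, adjusted p = 1.80e-08), macrophage and dendritic cell genes by 0.58 (13 of 18, adjusted p = 1.71e-05), hepatocyte genes by 0.49 (10 of 13, adjusted p = 0.0346), hypoxia and glycolysis genes by 0.26 (12 of 14, adjusted p = 0.00424) and immediate early genes by 0.20 (9 of 12, adjusted p = 0.0178). Smooth muscle genes were lower by -1.19 (16 of 16, adjusted p = 1.53e-07), luminal urothelium genes by -0.82 (17 of 18, adjusted p = 8.24e-05) and endothelial genes by -0.22 (10 of 12, adjusted p = 0.00133). Hepatocyte genes had an adjusted p = 0.83 with an estimated correlation, and the other 8 lists 0.775. Without metastasis 1, mitosis (0.22), E2F (0.19) and macrophages (0.31) were smaller but still called, and hypoxia (0.14) and immediate early genes (0.13) lost their calls. Hepatocytes lost theirs without metastasis 2 (0.07), without control bladder 2 (0.44) and, through the shared spread, without bladder tumor 6 (0.49), and immediate early genes without control bladder 1 (0.16), where endothelium stayed called at -0.15. Without the 8 near-mean arrays these 9 lists stayed called in the same direction, among 11 called, against control bladders 1 and 2 alone. The differences were -2.65 for smooth muscle, -1.77 for luminal urothelium, -0.45 for endothelium, 1.45 for macrophages, 1.09 for mitosis, 0.87 for E2F, 1.14 for hepatocytes, 0.56 for hypoxia and 0.46 for immediate early genes, and neutrophils (0.80) and antigen presentation (0.38) made up the 11. None of the 11 held with an estimated correlation (lowest adjusted p = 0.291). Without metastasis 1 as well, hypoxia (0.36), neutrophils (0.65) and antigen presentation (0.01) lost their calls, with mitosis at 0.56, E2F at 0.49 and hepatocytes at 1.92. Without metastasis 2, hepatocytes (0.37) lost theirs, with antigen presentation at 0.74.

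Among members, Ccna2, cyclin A2, was at 6.78 ± 0.72 in metastasis (n = 4) and 5.88 ± 0.40 in control (n = 5), Birc5 at 5.30 ± 0.16 and 4.91 ± 0.20, and Mcm2 at 5.67 ± 0.45 and 5.12 ± 0.28. C1qa and C1qc, subunits of complement C1q made by macrophages, were at 6.62 ± 1.09 against 5.56 ± 0.54 and at 6.13 ± 0.24 against 5.69 ± 0.21. Pcp4 was at 6.94 ± 0.87 and 8.46 ± 1.24, Kcnmb1 at 5.25 ± 0.19 and 5.98 ± 0.61, Cldn4 at 5.21 ± 0.73 and 6.87 ± 0.44, and Tek at 5.70 ± 0.17 and 6.22 ± 0.39. Dusp1, a phosphatase induced by stress, was at 6.42 ± 0.87 and 5.24 ± 0.43, and Pgk1, a glycolytic enzyme, at 7.64 ± 0.92 and 6.18 ± 0.64. No gene passed over all genes. Adjusted over the list alone, 1 endothelial, 1 hepatocyte and 1 EMT gene passed. limma called 0 genes, with 2146 at an unadjusted level of 0.05, 1 (lower) without bladder tumor 1, and 0 with array weights or a trended, robust prior. The smallest p belonged to Zfp354b (-0.79), Hspa13 (0.54 higher) and B130024G19Rik (-0.84), each with adjusted p = 0.532, and to Cep76 (0.45) and Gm26688 (-0.53), with adjusted p = 0.627. Without the 8 arrays, limma called 5 genes: Ahsg (5.10 higher), Lyz1 (4.03), Prg4 (2.83), Ctsk (2.25) and Xist (-6.20), with adjusted p from 1.20e-05 to 0.00147. With 1 further array left out the count was 64 without bladder tumor 7 (14 higher, 50 lower), 29 without metastasis 2 (28 higher), 13 without metastasis 1 (12 higher), 12 without bladder tumor 1 (10 higher) and 9 without bladder tumor 6 (8 higher). It was 7 without bladder tumor 2, 6 without control bladder 2 and 5 in the other 4 fits. The bladder tumors enter these counts only through the spread all groups share. With array weights the count was 263 (168 higher, 95 lower). These fits compare 2 metastases or fewer with 2 controls or fewer, so none of these counts settles how many genes differ. The chemosensory receptor mean differed by -0.04, with an exact two-sided permutation p of 0.619.

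The lone treated metastasis was set beside the 4 untreated ones, with no test. The 5 genes furthest above them included 4 immunoglobulin genes: Igkv4-91 at 13.3 against a mean of 5.00 ± 0.62 (SD, n = 4), Ighv12-3 at 11.7 against 8.44 ± 0.47, a further kappa light chain variable gene at 10.13 against 6.96 ± 0.57, and Ighm, the IgM heavy chain, at 9.09 against 6.03 ± 0.61. The fifth, Lgals1 (galectin-1), was at 14.06 against 11.01 ± 1.09. The 5 genes furthest below were Sptssb (3.74 against 7.05 ± 1.79), the glutathione transferase gene Gstm1 (5.95 against 9.13 ± 2.15), Sprr2b (2.84 against 5.37 ± 1.5), the uroplakin gene Upk3a (3.24 against 5.77 ± 1.28) and Gsdmc2 (3.81 against 6.28 ± 1.12). All 10 also lay outside the range of metastases 1 and 2 alone. Of 30142 genes, 10096 lay outside the range of the 4 untreated metastases, where chance would put 40% of genes outside. Of the 30 lists 11 lay outside that range, where the same 40% would by chance. Above it were fibroblast and matrix genes (7.36 against 6.50 to 6.86 in the untreated metastases), B and plasma cells (5.42 against 4.92 to 5.18), EMT regulators (6.58 against 6.00 to 6.55), unfolded protein response (7.16 against 6.53 to 7.11) and skeletal muscle (5.54 against 5.17 to 5.48). Below it were luminal urothelium (5.13 against 5.15 to 6.30), basal and squamous genes (4.98 against 5.08 to 5.57), smooth muscle (5.36 against 5.43 to 6.46), endothelium (5.47 against 5.54 to 5.68), neutrophils (5.49 against 5.53 to 5.84) and germline genes (4.955 against 4.964 to 5.11). The mitosis list, at 6.58, lay inside their range of 5.73 to 6.79, and T cell genes, at 5.09, inside 5.02 to 5.33.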

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

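The tests of tumor cell share, of treatment and of gene counts over other splits were chosen after the result was seen; those of background and of list counts over other splits were written down before. Outlying arrays were sought in 105 groups of values (35 measures in 3 groups), and 15 were found where chance gives about 5.25. That chance figure takes the arrays of a group to share a common spread. The outliers lie in control bladder, bladder tumor and metastasis, which all hold near-mean arrays close to each other, so another array stands out more easily. The measures also share arrays. The excess over 5.25 therefore cannot tell whether more arrays are outlying than by chance.

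Metastasis 1 lay far above the other 3 metastases for mitosis (6.79, others 5.73 to 5.82), E2F and replication (6.54, others 5.72 to 5.81), the engineered loci (7.29, others 6.19 to 6.32), antigen presentation (7.23, others 6.50 to 6.51) and neutrophil genes (5.84, others 5.53 to 5.57), and below them for chemosensory receptor genes (4.66, others 4.89 to 4.93). Bladder tumor 6 lay above the other 6 tumors for interferon response (6.34, others 5.40 to 5.79), neutrophil genes (6.85, others 5.25 to 5.85), EMT regulators (6.87, others 5.50 to 6.05), unfolded protein response (7.35, others 6.32 to 6.65) and hypoxia and glycolysis (7.10, others 6.00 to 6.26). Bladder tumor 7 lay above the other tumors for luminal urothelium (8.52, others 5.32 to 6.48) and smooth muscle genes (8.91, others 5.37 to 6.49). Metastasis 2 lay above the other metastases for hepatocyte genes (6.94, others 5.09 to 5.39). Control bladder 1 lay below the other controls for chemosensory receptor genes (4.82, others 4.89 to 4.91).

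In 3 lists every treated bladder lay on one side of the tumor mean and the treated metastasis on the other side of the untreated metastasis mean; the difference was not tested, since there is 1 treated metastasis. Macrophage and dendritic cell genes were 0.21 higher in the treated metastasis and -0.29 to -0.06 in the treated bladders. Skeletal muscle genes were 0.18 higher and -0.17 to -0.02. Immediate early genes were 0.21 higher and -0.30 to -0.06. The untreated mean includes the near-mean metastases 3 and 4. Against metastases 1 and 2 alone, the treated metastasis lay lower for macrophages (6.68 against a mean of 6.96), so the opposite direction for this list depends on the near-mean arrays. For immediate early genes it lay within their range (5.49 against 5.30 to 5.50), and for skeletal muscle above their mean (5.54 against 5.24).

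The lower cell cycle lists in treated bladder than in tumor were weighed against background, tissue mix and the treatment itself. With the chemosensory receptor mean as a covariate the mitosis difference kept a share of 0.67 of its size, between the bounds set for excluding background and for accepting it as the cause. The test of tissue mix assumed that a lower share of tumor cells raises smooth muscle and fibroblast markers alike. Their list scores moved 0.71 apart, but an exact permutation of the 10 samples gave p = 0.4. The assumption itself is in doubt, since tumor minus control was -0.69 for smooth muscle and -0.05 for fibroblasts. This test therefore cannot speak to the share of tumor cells, which stays open. The mitosis score itself gave an exact permutation p of 0.275 over 120 splits, with 2 of 3 treated bladders below the tumor mean and all 3 within the range of the tumors. Background, tissue mix and treatment cannot be told apart here, because none of these tests decided. The mitosis scores of the 3 treated bladders (5.34 to 6.00) lie within those of the tumors (5.30 to 6.62).

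Other splits of the same samples into groups of the same sizes do not allow chance to be excluded for the called lists of any comparison. For genes the count decides nothing: 0 were called in each real split, so all 100 splits (56 for treated bladder against control) had to give as many. The highest counts in other splits were 14 for tumor against control, 1353 for treated bladder against tumor, 20 for metastasis against tumor, and 0 for treated bladder against control and for metastasis against control. The split with 1353 genes set bladder tumor 6, bladder tumor 7 and treated bladder 2 against the rest. It was the only one of the 100 with over 100 genes, and 13 gave any. It points to a structure of the samples, which no test here addressed; these 3 arrays also had the lowest chemosensory receptor means of the 10, at 4.64, 4.85 and 4.78. The split with 20 genes set bladder tumor 1 and 2 with metastasis 3 and 4. For called lists, as many as the real 8 in tumor against control came in 34 of 100 splits (highest 16), as many as 12 in treated bladder against tumor in 12 of 100 (highest 16), as many as 4 in treated bladder against control in 41 of 56 (highest 11), as many as 8 in metastasis against tumor in 58 of 100 (highest 17), and as many as 9 in metastasis against control in 27 of 100 (highest 13).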

How the results depend on the processing

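The gene counts of 0 stayed at 0 under most settings. In metastasis against tumor, 2 genes were called with array weights, 2 among brighter genes only and 0 to 2 when single arrays were left out (2 without bladder tumor 6 and 2 without control bladder 5). In metastasis against control, 1 was called with the 2 groups alone and 0 to 1 with single arrays left out (1 without bladder tumor 1). In the other 3 comparisons none of the 19 fits that left out 1 array called a gene. Of settings chosen after seeing the data, leaving out the 8 near-mean arrays gave 1, 0, 1, 4 and 5 genes in the order reported. The same with 1 further array left out gave 1 to 59, 0, 1 to 2, 4 to 41 and 5 to 64 over all 11 such fits, and with array weights 48, 0, 1, 4 and 263. Leaving out 7 of the 8, all but bladder tumor 3, gave 1, 0, 1, 4 and 7, and with array weights 11, 0, 3, 4 and 383. A group left with 1 array in such a fit is taken to vary like the others. Also chosen after seeing the data, the chemosensory covariate gave 1 in metastasis against tumor and 3 in metastasis against control, and dropping predicted, small RNA and chemosensory genes gave 2 in metastasis against tumor. Genes that passed in both directions numbered 0 in every fit run. The cause of these shifts was not tested.

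Of the 41 called lists, 0 stayed called with an estimated correlation and 0 with fry. Of the 25 in comparisons without treated bladder, 0 stayed called among the 8 near-mean arrays alone. This is no test of the calls, because the 8 were chosen for lacking deviations shared with other arrays, those of their own group included. Leaving out single arrays gave 33 to 46 calls in all, and 11 of the 41 stayed called in every such fit. Without the 8 there were 56 calls, 46 to 61 with 1 further array left out, and 21 of the 56 stayed called throughout; with array weights there were 52, and without 7 of the 8, 58 (56 with array weights). The near-mean set as a covariate kept 41, but the 8 lie close to the mean of the other 12, so it can move little and says nothing about stability. Averaging rows kept 41, the 2 groups alone 37, quantile normalization 36, array weights 35, median centring 34, brighter genes 28 and the chemosensory covariate 27.

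Deviations of same-numbered samples correlated at r from -0.51 to 0.44, above 0.1 in every pair of no comparison, so no pairing was shown. In treated bladder against tumor, 1 of 3 pairs lay above 0.1. Some pairs hold a near-mean array, chosen for low correlation with every other array, so this check cannot exclude a pairing. The replicate block kept 24 of the 41 lists and called 5 genes in treated bladder against control, from 2 shared numbers, and 0 in the other 4 comparisons. In treated bladder against tumor it turned 4 lists: neutrophils 0.011, EMT 0.034, fibroblasts 0.0064 and hypoxia 0.057. No more than 1 sample per comparison correlated best with its own number.

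Interferon response in treated bladder against tumor ran from -0.30 to 0.05 over left-out arrays, turning without bladder tumor 6 (0.014) and treated bladder 1 (0.053), and was 0.013 with the chemosensory covariate. With the 8 and 1 further array left out it ran from -0.35 to 0.043, luminal urothelium from -0.057 to 1.01, EMT regulators from -0.42 to 0.033 and hypoxia from -0.40 to 0.028. That covariate also turned EMT (0.051) and unfolded protein response (0.032) in treated bladder against control. Among the 8 near-mean arrays the choice of arrays holds group differences down, so their signs carry no evidence. There, in tumor against control, E2F turned to -0.0073, neutrophils to -0.0098 and endothelium to 0.014. In metastasis against tumor, macrophages turned to -0.041, hepatocytes to -0.11 and skeletal muscle to 0.066. In metastasis against control, E2F turned to -0.014, mitosis to -0.011, macrophages to -0.16, hepatocytes to -0.11 and immediate early genes to -0.013. Genes outside the range of the untreated metastases numbered 9577 after median centring and 17471 against metastases 1 and 2 alone, where fewer arrays set the range. Signal over background was not computed, so the limit it sets is open.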

Other observations

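Y-linked and X-linked genes differed between arrays of one group. In control bladders 1 and 2, Eif2s3y averaged 5.02 and Uty 5.21, both on the Y chromosome, while Xist averaged 10.82. Across the other 10 arrays outside the near-mean set, Eif2s3y ran from 4.90 to 6.65 and Uty from 5.01 to 6.75. Bladder tumor 6 read low for both Y-linked genes (4.90 and 5.01) and, at 4.52, for Xist as well. The labels used here give no sex, and no test of sex was run. Differences from control bladders 1 and 2 alone therefore cannot be told apart from a difference of sex. This limit reaches the fits over all arrays too. Smooth muscle scores were 8.10 and 8.15 in these 2 controls, and 6.38 to 6.52 in the 8 near-mean arrays of 3 groups. Mitosis scores were 5.14 and 5.20, against 5.74 to 5.88 in the 8. For these lists, shifts against all 5 controls thus draw largely on the same 2 controls.

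All tests on the 8 near-mean arrays and on liver genes were chosen after the pattern was seen. If one set of arrays had been adjusted gene by gene to the mean of the other, the 8 arrays would follow the mean of the other 12 even where that mean is far from the median. Over 86 genes whose mean and median in the 12 arrays differ by more than 0.5, the slope was 1.13 (bootstrap interval over genes 1.02 to 1.28). Such an adjustment, which no label records, would give a slope near 1. The 8 were chosen for sharing no deviation from the mean of all arrays, which can by itself place them near that mean, so the slope cannot decide. A pool of equal parts of RNA from the other samples would sit at the log2 of their linear mean. The 8 arrays lay below it by a median of -1.15, and below it in 100% of these genes. Any arrays at the mean of the log2 values would lie below it in such skewed genes. The gap is thus no added evidence for an adjustment, and an uneven pool was not tested. Biology of the groups would make same-group arrays alike. Within the 8 the correlation within groups exceeded that between groups by 0.0037, but the 8 were chosen for low correlation with every other array, those of their own group included, so this value cannot tell. For smooth muscle the group differences of the other arrays are absent in the 8: scores ran from 6.38 to 6.52 over their 3 groups, and metastasis minus control was -0.05, against -2.65 without the 8. Not every list was so narrow: lung epithelium scores ran from 4.86 to 5.25 in the 8 and from 4.83 to 5.38 in the 12. These values describe the set and do not tell what made it so. An unrecorded adjustment stays open as a hypothesis, and which set was moved is not known.

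High Ahsg in the metastases was weighed against liver tissue in the sample. In metastasis 2 the mean of the other 12 hepatocyte markers was 6.65, against a highest value of 5.30 among 15 bladder arrays. Of the 12, 9 read above every bladder array, with Fgb (fibrinogen beta) at 9.75, Alb (albumin) at 9.53 and Hpx (hemopexin) at 8.31, but Apoc3 only just (5.32 against at most 5.30). Ttr (5.36 against at most 6.13), Cyp3a11 (5.03 against 5.51) and Cyp2e1 (6.26 against 6.64) did not. Liver tissue may account for Ahsg there, though not every marker was high. In metastasis 1 the same mean was 4.96, within the bladder range, with Alb at 5.06 and 1 marker (Cyp2e1, at 8.81) above every bladder array, although Ahsg read 10.6. In the treated metastasis Ahsg read 9.50 and the other markers averaged 5.25, also within the bladder range, but Alb (6.86 against at most 6.16) and Cyp2e1 (7.06 against at most 6.64) read above every bladder array, so liver tissue was neither shown nor excluded there. Liver admixture is argued against for metastasis 1, and the site of each metastasis is not given in the sources used here.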
